A study of Mus musculus with 11 samples.

How the data were processed

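Poly(A) RNA was sequenced from cardiac fibroblasts of injured left ventricles, 3 days after myocardial infarction, from 6 control libraries and 5 Pw1 CKO libraries. In the CKO mice, Pw1 (gene symbol Peg3) is deleted with a Pdgfra-driven Cre. The labels word the genotype in 2 ways, which splits the libraries into set 1 (replicates 1 to 3 of both groups) and set 2 (control 4 to 6 and 2 CKO libraries). The controls of the 2 sets are described differently in the labels. The columns of those 2 CKO libraries carry no matching replicate number, so they were placed in set 2 by elimination and are called CKO a and CKO b.

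The deposited table gives, per the file headers, TPM, FPKM and read counts for each library in 33 columns. The authors' TPM values are scaled to the transcripts of the whole library, and the deposited FPKM values are scaled to its fragments and to transcript length. The deposited counts are expected counts, estimated reads per gene that are mostly not whole numbers, and they were rounded before any test. The submitters named Bowtie2, RSEM, DESeq2 and the build GRCm38, with no versions or settings. The table was held in part: 1293 complete genes, in the text order of their gene IDs. Of these, 1141 had a value in every library and 152 were blank in at least 1 library and were left out of the tests. Peg3, Col1a1, Col1a2, Col3a1, Fn1, Postn and Acta2, which were to be reported whatever their result, were not among the genes held and were not analysed here. Gene positions came from the GRCm38.p6 gene table, which held 1275 of the gene IDs.

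Library totals were recovered from counts, FPKM and the effective transcript length that they imply, with 234 genes of FPKM of at least 5 for the first control library (95% interval 19896425 to 20625134 reads). CKO a and CKO b can be tied by name to their group but to no single sample, so only their counts were used and their 4 TPM and FPKM columns were not used here. Their library sizes, which set the CPM scale, were estimated from their reads on the genes held and the mean share held in CKO 1 to 3. The effective length of a gene was computed from counts and FPKM in the control libraries where the mean FPKM was at least 0.2. The mean transcript length of a library is 1000 times the ratio of TPM to FPKM, which is constant within a library and covers the whole library. GC content came from GENCODE M21 transcripts, which held 955 of the gene IDs.

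The test of single genes, its covariate, the gene lists and the naming rule were chosen before the data were examined. Counts were fitted in edgeR 4.0.16 under R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, 2-sided) with group and label set in the model, and Benjamini-Hochberg adjusted p under 0.05 was called. Effects within each set and their difference came from 1 fit with a mean for each group in each set. Changes are given as log2 of CKO over control, with the standard error implied by the F statistic, and levels as TMM-scaled CPM with the SD over libraries. The named genes are the 8 largest rises and 8 largest falls among called genes with average log2 CPM of at least 1 and the same sign in both sets, leaving out predicted gene names, and up to 4 members of each list described.

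Of 32 fixed gene lists, 20 had no member among the genes held. The lists with a tested member were imprinted genes, collagens, ECM glycoproteins, matrix proteases and inhibitors, cell cycle, interferon response, fatty acid and adipogenic, ribosomal proteins, macrophage and monocyte, erythroid, and unfolded protein response. Lists with at least 2 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) and fry. Groups of genes assembled from the symbols in the table were chosen after the values were seen and stand among the other observations.

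Mean transcript length and the slope of counts on length were compared between groups with exact 2-sided permutation tests, which were chosen after the data were seen. The splits over all libraries took no account of the label set. The trend of each library with transcript length, or with length and GC content, was removed by loess offsets (span 0.5) as an alternative chosen after seeing the data. Further alternatives were DESeq2 1.42.0 size factors and Wald test, limma-voom, no set term, replicate number as a block, other filters, each set alone, and each library left out in turn. Recovered totals as the only scaling and limma on log2(TPM + 1), both over the 9 libraries matched to a sample, were added after the data were seen. The TPM filter asked for a TPM of at least 1 in more of these libraries than the 3 CKO libraries among them. A gene above that level in the CKO libraries alone therefore could not be tested with TPM.

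The steps were tested on simulated data with the depth and spread of these libraries. Of genes changed 1.5-fold, 58.1% were called, of those changed 2-fold 89.1%, and of those changed 4-fold 100%, with 4.35% of calls false. With no changed gene, 0 of 750 genes were called by edgeR. A simulated length trend alone gave 257 calls of 734 genes without the length correction and 0 with it. That trend was linear in log2 length and the same in every CKO library. Removal of trends of other shapes, or of trends that differ between CKO libraries, was not simulated. A 2-fold difference between the sets was called for 46.3% of the simulated genes.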

Results

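RNA of cardiac fibroblasts was compared between 6 control and 5 Pw1 CKO libraries, all from infarcted left ventricles at day 3. Recovered library totals were 20206388 to 20491198 reads in the 6 control libraries and 20198426 to 20441312 in CKO 1 to 3. The genes held made up 3.02% to 3.11% of the reads of the control libraries and 2.91% to 2.94% of those of CKO 1 to 3. CKO a and CKO b had 535048 and 542843 reads on the genes held, against 592881 to 637764 in the other libraries, and their totals were not recovered. The first principal component of log2 CPM took 73.2% of the variance and separated the 6 control from the 5 CKO libraries.

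The series asked how Pw1 regulates extracellular matrix genes in these fibroblasts, and the comparison of CKO with control fibroblasts addresses that question for the genes held. Col16a1, a fibril-associated collagen (gene ID 107581, GRCm38 chromosome 4, 130047817 to 130099277), fell by 2.49 on the log2 scale (SE 0.11), from 122 ± 15.2 CPM (SD, n = 6) to 23.2 ± 7.30 CPM (SD, n = 5). All 3 tested ADAMTS metalloproteases, secreted enzymes that cut matrix proteins, were lower in CKO fibroblasts. Col16a1 and these 3 genes have transcripts over 4000 nt, a length at which 150 of 206 genes fell. Of the 2 tested ECM glycoproteins, Emilin1 was called higher with TMM and Ltbp4 was not called. Of the listed symbols, 1 of 40 collagens, 3 of 50 matrix proteases and inhibitors and 2 of 79 glycoproteins were tested. Unc5b, a netrin receptor (107449, chromosome 10, 60762594 to 60831581), fell by 2.60 (SE 0.22), from 73.7 ± 3.86 to 13.4 ± 6.28 CPM. Cmtm7, a membrane protein of the CKLF-like family (102545, chromosome 9, 114756836 to 114781993), rose by 2.45 (SE 0.14), from 20.3 ± 1.95 to 112 ± 26.0 CPM. Eif4ebp3, a translational repressor that binds eIF4E (108112, chromosome 18, 36664060 to 36666324), rose by 2.76 (SE 0.25), from 8.57 ± 0.752 to 60.6 ± 30.7 CPM.

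In the edgeR test, 549 of 770 genes (71.3%) differed between the groups, 261 higher and 288 lower in CKO fibroblasts, and 562 had an unadjusted p under 0.05. The calls with a change of at least 2-fold were 293, of which 135 rose and 158 fell. Of the 27 calls with a change of at least 8-fold, 21 were of genes with predicted names, against 192 of all 770 tested genes. These 21 genes are not named below. Lower genes were 52.5% of the calls with TMM, whose median change over all genes was -0.06. In the 9 libraries with a recovered total, TMM gave 530 calls of 802 genes, 270 higher and 260 lower (49.1% lower, median 0.01), and that total as the scaling gave 536 calls, 176 higher and 360 lower (67.2% lower, median -0.32). In the same libraries, limma on log2(TPM + 1) gave 522 calls of 654 genes, 77 higher and 445 lower (85.2% lower, median -0.62). Of the edgeR calls of the main test over all libraries, 488 were tested with TPM and 56 were called in the opposite direction. The TPM filter could pass a gene seen only in the control libraries but not a gene seen only in the CKO libraries. The share of lower genes with TPM can therefore also reflect this filter, which was not separated from the scaling. Directions below are those relative to TMM, and some of them depend on that choice, those of Ly6c2 and Emilin1 among them.

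**Figure D1:**
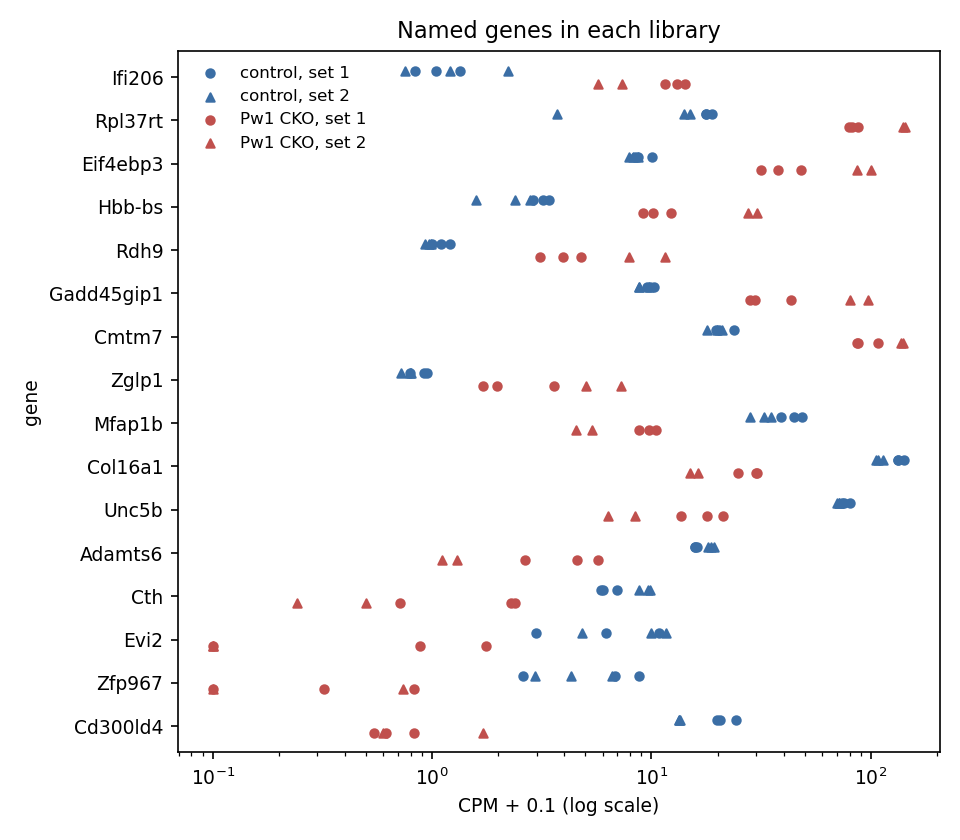
Levels in each library of the 16 genes named for large changes, as CPM plus 0.1 on a log axis. Predicted gene names were left out. Points are single libraries, control in blue and Pw1 CKO in red, with circles for set 1 and triangles for set 2; the control and CKO points of Col16a1 lie at 105 to 141 and 14.9 to 30.3 CPM.

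Among the other large rises, Ifi206, an interferon-inducible p200 family gene (102639543, chromosome 1), rose by 3.09 (SE 0.34), from 1.14 ± 0.533 to 10.3 ± 3.69 CPM. Rdh9, a retinol dehydrogenase family gene, rose by 2.65 (SE 0.28), and Gadd45gip1, a protein of the mitochondrial ribosome, by 2.47 (SE 0.27). Zglp1, a zinc-finger gene, rose by 2.31 (SE 0.33) from 0.728 ± 0.0853 CPM. Rpl37rt, a retrotransposed copy of a ribosomal protein gene, rose by 2.88 (SE 0.37), from 14.4 ± 5.61 to 106 ± 32.1 CPM. Among the other large falls, Cth, the cystathionine gamma-lyase of cysteine synthesis, fell by 2.79 (SE 0.52), from 7.75 ± 1.79 to 1.12 ± 1.03 CPM. Evi2 fell by 3.94 (SE 0.84), with CKO 2, CKO a and CKO b at 0, so the size of its fall rests on CKO 1 and CKO 3 and was -5.14 without CKO 3. Cd300ld4 fell by 4.53 (SE 0.33), from 17.4 ± 4.73 to 0.759 ± 0.486 CPM, Zfp967 by 4.06 (SE 0.67), and Mfap1b by 2.41 (SE 0.13). Cd300ld4, Zfp967, Mfap1b, Rpl37rt and the beta-globin genes have near-identical copies in the mouse genome that can share reads, so their levels are uncertain. These 16 genes kept their direction and their call with recovered totals, with TPM and after the length correction, where tested. Ifi206 and Rdh9 were not tested with TPM, since their levels in the control libraries were too low for its filter. The sizes of several changes did depend on the correction: after it, Hbb-bs was at 1.09, Rpl37rt at 1.41 and Zglp1 at 1.22 (0.55 with TPM). Ranked after the length correction, without the condition on signs in both sets, Hbb-bs, Rpl37rt, Cmtm7, Zglp1 and Col16a1 were not among the largest changes, and Wdr92, Cfap43, Nsun5, Zfp984 and Bsdc1 were.

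Of the fixed lists on the extracellular matrix, collagens had 1 tested member, Col16a1, which fell (1 called adjusted over the list alone). Matrix proteases and inhibitors had 3 tested members and all fell: Adamts6 by 2.65 (SE 0.37), Adamts9 by 1.34 (SE 0.08) and Adamts7 by 1.24 (SE 0.09), with 3 called adjusted over the list alone. After the length correction, their changes were smaller, at -1.85, -0.37 and -0.61 in that order. ECM glycoproteins had 2 tested members. Emilin1, an elastin-associated glycoprotein, rose by 0.61 (SE 0.16) with TMM and was lower, at -0.50, with TPM (-0.0901 with recovered totals). Its rise was 0.19 in set 1, where it was not called, and 1.09 in set 2, and 1 member of the list was called adjusted over the list alone. Ltbp4, which binds latent TGF-beta, changed by -0.08 (SE 0.11; edgeR adjusted p = 0.530). It was called higher after the length correction, at 0.58, and lower with recovered totals, at -0.60, with TPM, at -1.02, and in set 1 alone, at -0.33, so its direction is open. Camera gave adjusted p = 0.0565 for the proteases (unadjusted 0.0141), which became adjusted p = 0.182 with an estimated correlation, and adjusted p = 0.623 for the glycoproteins (0.732 with an estimated correlation). Without CKO b, the proteases passed with adjusted p = 0.0489. The collagens and matrix genes named in the design of the comparison, Col1a1 and Fn1 among them, were not analysed here.

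The cell cycle list had 2 tested members, both lower and both called adjusted over the list alone: Cenpf, a kinetochore protein, fell by 2.27 (SE 0.15), and Cdc20, an activator of the anaphase-promoting complex, by 0.52 (SE 0.07), with camera adjusted p = 0.113. Dio3, the 1 imprinted gene tested, changed by -1.0 (SE 0.46; edgeR adjusted p = 0.0726; 0 called adjusted over the list alone) and was called lower without CKO b, at -1.38, with limma-voom, at -1.29, with recovered totals, at -1.31, with TPM, at -0.76, and after the length correction, at -1.41. Isg15, of the interferon list, changed by -0.11 (SE 0.13; edgeR adjusted p = 0.453; 0 called adjusted over the list alone) and was called lower with TPM, at -0.76. Dnajc3, of the unfolded protein response list, changed by 0.09 (SE 0.05; edgeR adjusted p = 0.128; 0 called adjusted over the list alone) and was called lower with recovered totals, at -0.20, and with TPM, at -0.64, but higher after the length correction, at 0.78. Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, fell by 0.63 (SE 0.09; 1 called adjusted over the list alone) and was higher, at 0.43, after the length correction.

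Among markers of other cells and of RNA quality, the beta-globins of red cells rose, Hbb-bs by 2.67 (SE 0.34), from 2.62 ± 0.656 to 17.8 ± 10.2 CPM, and Hbb-bt by 2.64 (SE 0.58; not called with recovered totals, at 1.98), with 2 called adjusted over the list alone and camera adjusted p = 0.140. Ly6c2, of the macrophage and monocyte list, rose by 1.01 (SE 0.21), from 67.0 ± 6.50 to 141 ± 71.2 CPM (1 called adjusted over the list alone), but was not called with recovered totals, at 0.17, or after the length correction, at -0.28, and was called lower, at -0.29, with TPM. Rpl5, of the ribosomal protein list, rose by 1.41 (SE 0.15), from 419 ± 54.3 to 1114 ± 244 CPM (1 called adjusted over the list alone), and by less with recovered totals, at 0.74, with TPM, at 0.26, and after the length correction, at 0.45. Across the 11 lists with a tested member, 5 of 16 members rose and 7 fell. Camera called 0 of the 4 lists it could test, with 1 at an unadjusted p under 0.05, against 3 called by fry, which asks whether the members of a list move 1 way without comparing them with other genes.

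The length of the transcripts that a gene makes went with its direction. Genes with transcripts under 1000 nt mostly rose (35 rose and 6 fell of 51, median change 1.47), as did those of 1000 to 2000 nt (107 rose and 22 fell of 190, median 0.58). Genes of 2000 to 4000 nt went both ways (91 rose and 105 fell of 291, median -0.08), and those over 4000 nt mostly fell (14 rose and 150 fell of 206, median -0.72). These counts are relative to TMM. With recovered totals, the genes of 2000 to 4000 nt had 42 rises and 136 falls of 292, and with TPM 17 rises and 191 falls of 251. With TPM, the genes of 1000 to 2000 nt had 32 rises and 66 falls of 167, and those under 1000 nt had 26 rises and 16 falls of 54 (median 0.29). The TPM filter could not pass genes seen only in the CKO libraries, which can lower the count of rises. With recovered totals, the genes under 1000 nt had 35 rises and 11 falls of 55 (median 0.92). Across the 738 genes with a length, change and length had Spearman's rho of -0.49 (Pearson -0.39; permutation p = 0.0001, the smallest that the permutations can give), where genes are not independent replicates.

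**Figure D2:**
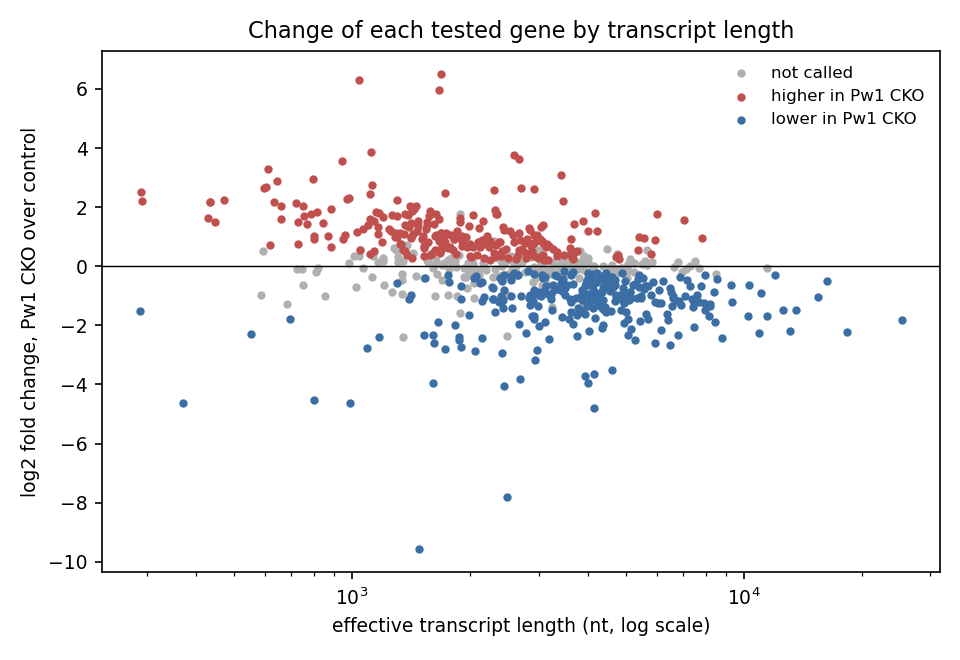
Change of each tested gene (log2 of Pw1 CKO over control) against its effective transcript length in nt, on a log axis. Red and blue points are genes called higher and lower and grey points are not called; the median length was 1794 nt for the genes that rose and 4118 nt for those that fell.

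The mean transcript length of a whole library was 2221 ± 52.7 nt in control (SD, n = 6) and 1626 ± 75 nt in CKO 1 to 3 (SD, n = 3), a difference of -595 nt (exact permutation test, 2-sided p = 0.0238, the smallest that 84 splits allow). Within set 1 the difference was -606 nt (n = 3 and 3, exact permutation p = 0.1, the smallest possible), and set 2 gave no value because CKO a and CKO b entered with counts only. With CKO 1, CKO 2 or CKO 3 left out in turn, the exact permutation p was 0.0714, the smallest then possible. The counts of all 11 libraries gave a slope of log2 count per doubling of transcript length, which was 0.68 to 0.77 in the control libraries, 0.19 to 0.31 in CKO 1 to 3, and 0.021 and 0.025 in CKO a and CKO b. The slope differed between CKO and control by -0.56 (n = 6 and 5, exact permutation test, 2-sided p = 0.00433, the smallest possible), over splits that ignored the label set. It differed by -0.46 within set 1 (exact permutation p = 0.1, the smallest possible) and by -0.71 within set 2 (exact permutation p = 0.2, the smallest possible). The 10 most abundant genes took 15.2% to 16.2% of the held reads in the control libraries and 21.8% to 31.6% in the CKO libraries.

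**Figure D3:**
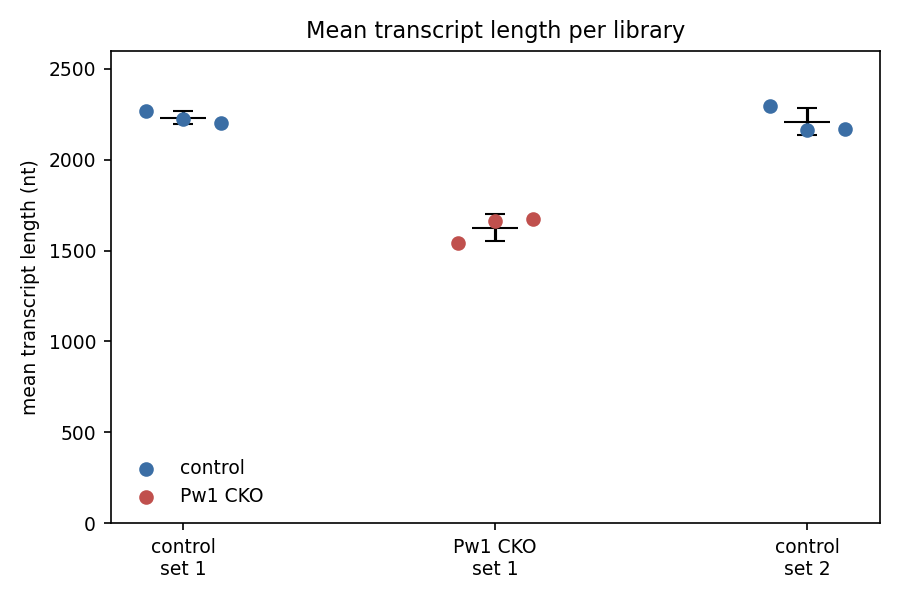
Mean transcript length in nt of each library by group and label set, for the 9 libraries matched to a sample, with bars for the mean and SD. CKO 1 to 3 lie between 1540 and 1675 nt and the 6 control libraries between 2167 and 2294 nt.

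With the length trend of each library removed, 515 of 738 genes were called, 258 higher and 257 lower. Of the 529 calls among these genes without the correction, 381 (72.0%) kept their direction and their call, 34 were called in the opposite direction and 114 were no longer called. Col16a1 fell by 1.81 (SE 0.07) after the correction, Unc5b by 1.84 (SE 0.17), Adamts6 by 1.85 (SE 0.32), Adamts9 by 0.37 (SE 0.07) and Cenpf by 1.12 (SE 0.13). With GC content corrected as well, Adamts9 was no longer called (-0.18; edgeR adjusted p = 0.0669). Cmtm7 stayed higher by 1.5 (SE 0.07) and Eif4ebp3 by 1.81 (SE 0.18). Hbb-bt was no longer called (1.08, SE 0.55, against 2.64, SE 0.58, before), and Isg15 was called lower at -1.47 (SE 0.15).

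The label sets allow the CKO effect to be measured separately in each. Adamts6 fell by 1.90 in set 1 and by 4.08 in set 2, Cth changed by -1.85 and -5.07, and Unc5b fell by 2.12 and 3.30. Hbb-bs rose by 1.76 in set 1 and 3.72 in set 2, and Gadd45gip1 by 1.77 and 3.28. Ifi206 rose by 3.71 in set 1 and by 2.28 in set 2. Col16a1 fell by 2.25 and 2.82, and Adamts9 by 1.32 and 1.39.

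In set 1, 525 of 844 genes were called, 252 higher and 273 lower, and in set 2, 596 of them, 283 higher and 313 lower. Of 456 genes called in both sets, 439 had the same direction and 17 the opposite, among them Ahnak2 (-0.39 in set 1 and 0.37 in set 2), which was picked after its values were seen. The test of the difference itself called 324 genes, 406 with an unadjusted p under 0.05. Of the 324, 267 had the same direction in both sets, 250 of these with the larger change in set 2, and 57 had opposite directions. The tally of selected genes does not by itself speak for all genes. Over all 844 genes, called or not, the least-squares slope of the change in set 2 on that in set 1 was 1.02. Noise in the set 1 values flattens such a slope, so it does not establish equal effects. The median change was larger in size in set 2 in each length class. It was 1.53 against 1.21 in set 1 under 1000 nt, and -0.94 against -0.62 over 4000 nt. Leaving out 1 library at a time gave 217 to 391 genes with a set difference. Set 2 holds 2 CKO libraries, whose columns differ in their blanks from the control columns of set 2. Of the genes with blanks, 70 were blank only in these 2 CKO libraries, and 58 had values only in the set 2 controls. The way the columns were joined therefore cannot be separated from the difference between the sets. Nor can it be separated from the CKO effect within set 2, with its 596 calls, or from the part of set 2 in the pooled calls.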

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

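The test of library quality within the CKO group and the joint test of length and GC content were chosen only after the result was seen. Levels of 4 named genes had 1 library far from the others of its group, where chance gives about 1 in 20 of the 62 groups looked at. The gap over the range was 0.680 for Rpl37rt in control 4 (3.60 CPM against 14 to 18.8 in the others) and 0.651 for Eif4ebp3 in control 1 (9.99 against 7.81 to 8.57). It was 0.757 for Cd300ld4 in CKO b (1.61 against 0.445 to 0.727) and 0.756 for Acaca in CKO 3 (26.4 against 29.3 to 30.2).

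The CKO effect differed between the label sets for 324 genes. The change in set 2 minus that in set 1 was 1.96 for Hbb-bs, 1.58 for Zglp1, 1.53 for Rdh9, 1.5 for Gadd45gip1, 1.48 for Rpl37rt, 1.37 for Eif4ebp3 and 0.67 for Cmtm7. It was 1.20 for Ly6c2, 0.90 for Emilin1, 0.83 for Rpl5, 0.52 for Ltbp4, 0.41 for Acaca and 1.58 for Cd300ld4. It was -3.22 for Cth, -2.19 for Adamts6, -1.43 for Ifi206, -1.18 for Unc5b, -0.56 for Col16a1 and -0.55 for Mfap1b. Rps27rt, left out of the tests because of blanks, had 23.21 estimated counts in both CKO a and CKO b and 0 in control 4 to 6.

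The calls between the groups, Col16a1, Unc5b and Cmtm7 among them, numbered 549, and 1 of 100 drawn splits of the libraries, the real one, gave as many. That is the smallest share that 100 splits can give, which argues against chance but does not exclude it. The highest other split gave 483 and was close to a mirror of the real one, with all 5 CKO libraries in 1 arm beside 1 control library. Within set 1, 525 genes were called and the highest other split gave 0; 1 of 10 splits gave as many, too few for a share under 0.05. A smooth length trend as the whole cause is argued against, since 72.0% of the 529 calls among genes with a length stayed after its removal. So is length with GC content as the whole cause. Of the 470 calls among genes with both, 64.0% were kept, 50 were called in the opposite direction and 119 were no longer called. The genotype remains an open, untested explanation, as does any difference in sample handling that goes with it. In set 2 the way the columns were joined also stays open, since its CKO and control columns differ in their blanks.

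Genes with long transcripts, Cenpf and Adamts9 among them, were lower in CKO fibroblasts. GC content in place of length is argued against, since the partial rank correlation of change with length at fixed GC was -0.57 (-0.63 to -0.51). A difference in RNA or library quality that also varies within a group cannot be told apart: CKO 1 against CKO 2 and 3 had a rank correlation with length of 0.294 in size (0.226 to 0.358), beside up to 0.307 among the controls. The slope of counts on length was lower in each of the 5 CKO libraries than in each of the 6 control libraries, so quality and genotype are confounded.

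Genes with a set difference, Adamts6 and Hbb-bs among them, mostly had the larger change in set 2, while the slope of set 2 on set 1 over all genes was 1.02. The median change in each class of transcript length was also larger in size in set 2. A steeper length trend in set 2 as the whole cause of these differences is argued against. Among genes with a length, 81.8% of the 329 called differences stayed after the trend was removed. A difference in the handling or joining of the 2 CKO libraries of set 2 stays open and untested. So does a difference between the mice or between the differently described controls of the 2 sets.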

How the results depend on the processing

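The corrections for length and GC content, recovered totals, TPM and all tests of mean transcript length and of the slope on length were chosen only after the result was seen. Of 203 planned values of named genes with all libraries or 1 set, 198 kept direction and call, 1 lost its call, 3 gained one and 1 reversed. With 1 library left out, 317 of 319 did. Of 143 values under the added settings, 110 did, 5 lost their call, 14 gained one and 14 reversed. The cause of the reversals was not tested. Ltbp4 reversed to 0.23 in set 2 alone, 0.58 after the length correction, 0.58 with the replicate block and the length correction, and 0.15 after length and GC correction, and ranged from -0.13 to 0.00475 with 1 library left out (the highest without CKO 2). Acaca reversed to 0.43, 0.42 and 0.63, and Ly6c2 to -0.28, -0.28 and -0.33, with the length correction, the block with it, and length and GC correction. Emilin1 lost its call in set 1 alone and Adamts9 after length and GC correction. With recovered totals Dnajc3 reversed to -0.20 and Emilin1 to -0.0901, and with TPM Dnajc3 to -0.64, Emilin1 to -0.50 and Ly6c2 to -0.29.

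The count of 549 genes became 293 with a change of at least 2-fold, by its construction, and lay between 440 and 587 under the other settings and between 519 and 563 with 1 library left out. It was 485 to 529 in set 1, 528 to 599 in set 2 and 217 to 391 for the difference with 1 library left out. Lists past camera numbered 0 to 1, with 1 without CKO b. The replicate block gave 529 genes and changed no call of a list. Same-numbered libraries deviated together with correlations of 0.10, 0.055 and 0.23, which does not establish pairing, although every library correlated best with its own number.

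The difference in mean transcript length was -606 nt in set 1 alone (exact permutation p = 0.1), and -619 to -551 nt with 1 library left out. The slope of log2 counts per doubling of length differed by -0.46 in set 1 (exact permutation p = 0.1) and -0.71 in set 2 (p = 0.2), and by -0.60 to -0.53 with 1 library left out. These p-values are the smallest that the sets allow, and mean length has no value in set 2. The setting planned for tables without counts, limma on log2(value + 1), was run only as an added setting, on TPM in the libraries matched to a sample. The difference between sets has no value in 1 set alone. The depth limits genes under about 1 CPM, such as Dio3 and Hbb-bt.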

Other observations

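The groups of genes below and their tests were chosen after the values were seen. Genes of the mitochondrial ribosome and respiratory chain rose together, 11 of 11 tested, with a median change of 1.60, among them Gadd45gip1 (2.47). Camera gave adjusted p = 0.000377, and adjusted p = 0.616 with an estimated correlation. With TPM, 6 of them rose and 1 fell, and after the length correction 7 rose and 2 fell, with camera adjusted p = 0.335. Their median transcript length was 1170 nt. Of 14 chromatin regulators, 9 fell and 3 rose (camera adjusted p = 0.323), after the length correction 8 fell and 4 rose, and with TPM 11 fell and 1 rose.

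Of 6 aminoacyl-tRNA synthetases, 4 fell and 1 rose (camera adjusted p = 0.402), and after the length correction 2 fell and 1 rose, with a median of -0.11 against -0.65, while with TPM all 6 fell. Of 15 genes of protein folding and glycosylation in the endoplasmic reticulum, 8 fell and 3 rose (camera adjusted p = 0.402), after the length correction 6 fell and 7 rose, and with TPM 13 fell and 0 rose. Of 9 genes of serine, glycine and one-carbon metabolism, 5 rose and 2 fell, Cth among the latter (camera adjusted p = 0.402). After the length correction 3 rose and 2 fell, with a median of 0.04 against 0.26, while with TPM 1 of 8 rose and 5 fell.

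LOC100044068, left out of the tests because of blanks and picked after its values were seen, had 2239 to 3459 estimated counts in the 6 control libraries, 0 in CKO 1 to 3 and no value in CKO a and CKO b.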
